A study of Mus musculus with 8 samples.

How the data were processed

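RNA was taken from GFP-positive cells sorted from cortex and lungs of Tie2-GFP mouse embryos at E13.5. Per the labels' protocols, the cortex was freed of meninges and choroid plexus, tissues were dissociated with collagenase, the sorted cells' RNA (15 to 30 ng) was linearly amplified, and the biotin-labelled product was hybridised to Affymetrix Mouse Genome arrays. Per the series' design text, all embryos of a litter (10 to 13) were pooled as a biological replicate, with 4 litters. The labels do not say whether samples with the same number come from the same litter.

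The authors deposited log2 expression values per probe set. The submitters' processing notes name RMA, which corrects background, normalizes arrays by quantiles and summarises probes, and the affy package, with no version given in the sources used here. The values ran from 2.82 to 15.02, with array medians of 6.59 to 6.72. RMA compresses differences near its lower end, so a fold against a group of low values understates the difference, and values carry no detection call. Normalizing cells of different tissues to one distribution makes every difference relative to the rest of the array. No depth applies to arrays, and their number (4 per tissue) limits the precision. All 8 columns of the table were mapped to a sample by their sample identifier, and 0 columns were left out.

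The 64 control probe sets were left out of the tests. Gene names came from the platform annotation as given for this work. Of the 45037 other probe sets, 34945 named 1 gene, 932 named several and 9160 were unnamed here. Of those with 1 gene, 34741 were found by gene number in the RefSeq table of mouse genes, and 0 symbols changed through it. Each gene was represented by its probe set with the highest mean over the 8 arrays, among those naming that gene alone, which gave 18193 genes. No filter on dim probe sets was used in the main analysis. Of 71 genes named, 43 had several probe sets, and for 4 of them (Foxl2, Foxf2, Aldoc and Sox9) another probe set had the opposite sign, in 0 cases with a call. An equal sign did not mean an equal size. Other probe sets lay near 0 for such genes as Acta2 (cortex minus lung -0.004), Cxadr (0.05), Itgb3 (-0.11), Lox (-0.28) and Cd44 (-0.34). Values per gene are those of the chosen probe set.

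Cortex and lung were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, tissue as the factor, no litter block). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes or probe sets tested. Calls were made at an adjusted p under 0.05, and also with a log2 difference of at least 1. Differences are cortex minus lung. SD and n are over the arrays of a tissue, and confidence intervals are at 95%.

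The 30 gene lists were written before the data were examined, from textbook knowledge. They were tested with camera at a preset correlation between genes of 0.01, and 14 passed, 4 towards cortex and 10 towards lung. With the correlation estimated from the data, 1 passed, the neural list. A further test, fry, asks whether a list's genes move on balance one way, and in its mixed form whether they change in either direction. Neither form compares the list with other genes. Fry called 8 lists, and 29 in its mixed form, all but the sex-linked genes. Lists overlap in part, and the counts of members were taken over all genes and again adjusted over the list alone. Members not named by the annotation were left out and are not analysed here.

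Genes were named by a rule fixed before the data were examined. It took the 6 largest differences towards each tissue among called genes whose arrays did not overlap between tissues, without symbols of unnamed transcripts. It also took the 2 called members of each list with the largest difference, or the largest member where none was called, and 12 genes chosen in advance (Tek, Pecam1, Cdh5, Slc2a1, Mfsd2a, Cldn5, Lef1, Foxq1, Plvap, Foxf1, Abcb1a and Icam2). Members of the neural list given as examples beyond this rule (Sox2, Dlx1 and Tbr1) were picked after their values were seen. The arrays of the tissues did not overlap for 4462 genes, 24.5%, where chance gives 2.86% for 4 against 4.

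The fit and the list test were tested on simulated data with the real gene means and residual spread over the 18193 genes, in which 200 genes were changed between cortex and lung. Of 100 genes changed by 2 log2 units 70 were called, and of 100 changed by 1 log2 unit 25 were called, all in the right direction. Of 98 calls 3 were false. The data gave 3291 called genes, so the adjustment set a stricter limit on p in the simulation than in the data. The shares called may therefore understate those of the real comparison. A list of 20 raised genes was called, and 0 of 29 unchanged lists were. The simulated noise was independent between genes. The list result therefore does not measure false calls of lists whose genes vary together, such as the pan-endothelial list (estimated correlation 0.85).

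Alternatives fixed beforehand were the sample number as a block, leaving out each array, quantile normalization or median centring of the deposited values, removal of dim probe sets (those not above the array median on at least 4 arrays), the mean of all probe sets of a gene, leaving out probe sets that can bind several transcripts, eBayes with an intensity trend and robust variances, array weights, a stricter threshold, a test against a 2-fold difference, an estimated correlation, and groups taken from the description field. Alternatives added after the data were seen were a shift of each array to the same mean of the pan-endothelial list, leaving out both arrays numbered 18, and the level of the bioB hybridization controls as a covariate. Figures were drawn with matplotlib 3.10.9.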

Results

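Gene expression was profiled in GFP-positive cells sorted from the cortex and the lungs of E13.5 mouse embryos. The embryos carried a Tie2-GFP transgene, in which the promoter of the endothelial receptor gene Tek (Tie2) drives green fluorescent protein, so that sorting on GFP takes up cells of blood vessels. Each of the 8 arrays held the cells of 1 tissue from a pooled litter of 10 to 13 embryos, with 4 arrays for cortex and 4 for lung. The samples carried the numbers 72, 22, 19 and 18 in both tissues. The comparison asks which genes distinguish the vessels of the developing brain, where the blood-brain barrier forms, from those of another organ of the same age. The deposited values were log2 intensities of 45101 probe sets, of which 45037 were not controls, and 18193 genes were tested. Array medians lay between 6.59 and 6.72, and the number of arrays limits the precision.

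Tissue was taken from the title, source name and tissue label of each sample. The description field of 4 samples, those numbered 19 and 18, names the other tissue, and the values went with the titles. The mean of the Hox genes, patterning genes of the trunk, lay at 6.48 ± 0.21 in the arrays titled lung and 5.20 ± 0.29 in those titled cortex. Hoxa5 and Neurod6 were added to this check after their values were seen. Hoxa5 lay at 10.56 ± 0.15 in the arrays titled lung and 6.49 ± 0.79 in those titled cortex (mean log2 value ± SD, n = 4 each). Neurod6, a gene of cortical neurons, lay at 11.71 ± 0.18 in cortex and 3.72 ± 0.49 in lung, with no overlap between the arrays of the tissues. The first principal component held 64.1% of the variance and separated all 4 cortex arrays from all 4 lung arrays. Correlations over probe sets ran from 0.924 to 0.984 within a tissue and from 0.876 to 0.940 between tissues, so no pair of arrays held the same values.

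Cortex and lung cells differed in 3291 of the 18193 genes at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1888 of them higher in cortex and 1403 higher in lung. A difference of at least 2-fold was called for 2336 genes, 1435 higher in cortex and 901 higher in lung. The balance over all called genes turned towards lung when arrays were centred on their medians (1660 towards cortex and 1732 towards lung), with array quality weights (2204 and 2233) and with the bioB covariate, chosen after the data were seen (1904 and 2055). Among genes at least 2-fold apart it stayed towards cortex in these (1325 and 1042, 1445 and 1125, and 1358 and 1152). At 16-fold or more the calls were 180 towards cortex and 39 towards lung. The genes with the largest differences towards cortex were transcripts of neurons and neural progenitors. They were the noncoding RNA Pantr1 (297-fold, adjusted p = 1.58e-06), Neurod6 (254-fold), the neuronal kinesin Kif5c (250-fold), the neuronal tubulin Tubb3 (150-fold), the radial glial lipid-binding protein Fabp7 (150-fold) and the G-protein subunit Gng3 (144-fold, adjusted p = 9.48e-06). Towards lung the largest were matrix Gla protein Mgp (130-fold, adjusted p = 2.45e-05), the sodium channel Scn7a (126-fold), elastin Eln (81.2-fold), the noncoding RNA Fendrr, which neighbours Foxf1 (79.6-fold), the elastic fibre protein Fbln5 (69.3-fold) and lysyl oxidase Lox (47.3-fold, adjusted p = 4.61e-05). Over probe sets, 5475 of 45037 were called, 3278 higher in cortex and 2197 higher in lung. When every array was shifted to the same mean of 26 pan-endothelial genes, a scaling chosen after the data were seen, the median gene lay 1.14 log2 units higher in cortex and the calls became 5242 towards cortex and 138 towards lung. Counts and medians of lists after this scaling carry this shift of all genes. A list median that turned to a value below 1.14 still lay below the median of all genes. Under this scaling limma gave every listed gene the same SE, 0.587, so that a call there is in effect a limit on the fold, and its calls and p-values do not weigh a gene's own spread.

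All 26 measured members of the neural list rose in cortex, over all genes and adjusted over the list alone, with a median difference of 5.14 log2 units. Tubb3 reached 12.70 ± 0.45 in cortex against 5.47 ± 0.50 in lung, the progenitor factor Sox2 11.33 ± 0.21 against 4.42 ± 0.45, the interneuron factor Dlx1 10.80 ± 0.60 against 5.27 ± 0.42, and the deep-layer factor Tbr1 10.51 ± 0.28 against 3.94 ± 0.12. The competitive test of the list over all genes gave an adjusted p of 4.94e-32, and adjusted p = 0.0436 with an estimated correlation. The mean of the neural list ranged from 10.70 to 11.25 on the cortex arrays and from 6.24 to 6.57 on the lung arrays. The cortex arrays with the lower neural means, numbers 19 and 22, had the higher pan-endothelial means, 11.16 and 10.998, against 9.64 for number 72 and 9.30 for number 18. Every group of genes described as higher in cortex was therefore measured beside these neural transcripts, and every group described as higher in lung beside a pan-endothelial mean of 10.27 ± 0.94 in cortex and 11.51 ± 0.27 in lung.

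**Figure D1:**
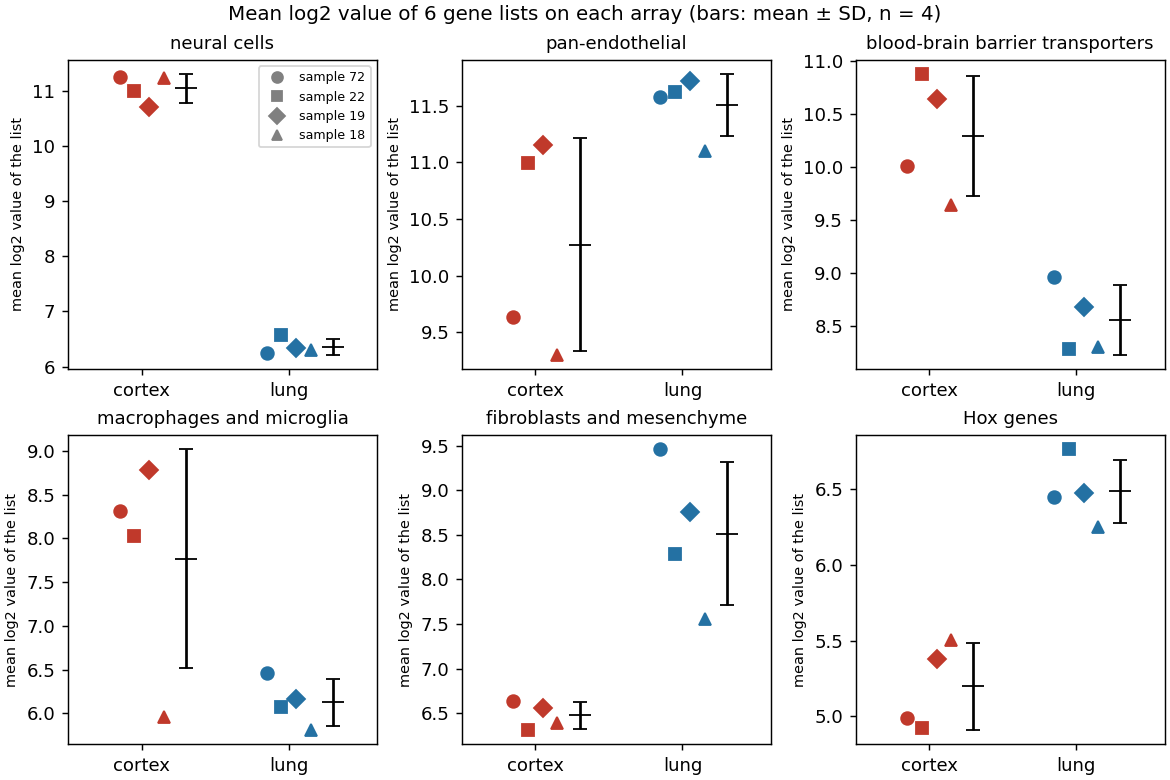
Each panel shows the mean log2 value of a gene list on each of the 8 arrays, cortex in red and lung in blue, with the symbol giving the sample number and the black bar the mean ± SD of the 4 arrays of a tissue; each vertical axis has its own range and does not start at 0. The neural means of the cortex arrays sit between 10.70 and 11.25, and the macrophage mean of cortex sample 18, 5.96, sits below those of the other cortex samples.

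Transporters of the blood-brain barrier rose in cortex in part. Of 25 measured members, 13 were higher in cortex, 1 was higher in lung and 11 were not called (14 and 1 adjusted over the list alone). The thyroid hormone carrier Slco1c1 was 49.99-fold higher, at 11.64 ± 0.94 against 5.998 ± 0.20 (adjusted p = 4.53e-05), and the lysophospholipid transporter Mfsd2a 49.9-fold, at 12.31 ± 0.63 against 6.67 ± 0.48 (adjusted p = 1.92e-05). The glucose transporter Slc2a1 (Glut1) was 1.99-fold higher, at 13.69 ± 0.35 against 12.70 ± 0.17 (adjusted p = 0.00883). The efflux pump Abcb1a (P-glycoprotein) did not pass, at 10.50 ± 1.13 against 9.59 ± 0.40 (adjusted p = 0.267), and the member higher in lung was Abcc1, named after its values were seen. The list as a whole was shifted towards cortex (adjusted p = 6.05e-07), but adjusted p = 0.59 with an estimated correlation. The call of Abcc1 ended without any 1 of the arrays other than cortex 72, leaving 0 members higher in lung. Pan-endothelial scaling gave 19 members higher in cortex and 0 in lung, with Abcb1a called (2.14 log2 units, adjusted p = 0.00242). Over the whole solute carrier family, 44 of 349 genes were higher in cortex, 32 higher in lung and 273 not called (52 and 35 adjusted over the list alone), with a list p of 0.71, and adjusted p = 0.941 with an estimated correlation. The median of that family was slightly below 0, -0.09, while its mean of 0.16 and its test lay towards cortex. Its largest difference, 96.8-fold, was that of Slc17a6, a vesicular glutamate transporter of neurons, and its count towards lung was 21 without cortex 72 and 17 without both arrays numbered 18. Pan-endothelial scaling gave 116 of the family towards cortex and 1 towards lung, with a median of 1.15.

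Regulators known from brain endothelium differed in part. Of 10 measured transcription factors of the brain endothelial list, 3 rose in cortex and 7 were not called (6 higher adjusted over the list alone). Foxl2 was 9.04-fold higher, Foxf2 8.75-fold and Foxq1 4.35-fold (adjusted p = 0.0103). Lef1, a partner of beta-catenin, lay at 11.25 ± 0.72 in cortex and 10.24 ± 0.40 in lung without passing (adjusted p = 0.0903), and it passed without cortex 72 (1.29 log2 units, adjusted p = 0.0361) and after pan-endothelial scaling (2.24 log2 units). The list was shifted towards cortex (adjusted p = 0.0134), with adjusted p = 0.651 with an estimated correlation and 0.187 without dim probe sets. Pan-endothelial scaling gave 8 of 10 higher in cortex, with the median moving from 0.96 to 2.20. Without cortex 18 the list had 5 members higher in cortex, and without cortex 22 it had 1 higher in lung. Among 25 measured genes of Wnt and beta-catenin signalling, 4 rose in cortex and 4 in lung (8 and 4 adjusted over the list alone), and 17 were not called. The Wnt target Apcdd1 was 8.11-fold higher in cortex (adjusted p = 0.000366), and the receptor Tnfrsf19 7.52-fold (adjusted p = 0.0381). The call of Tnfrsf19 ended without any 1 of cortex 72, 22, 19 and 18 and lung 22 and 19, with differences of 2.62 to 3.20 log2 units. The count towards lung fell to 1 without cortex 72 and to 2 without lung 72, 22 or 19, and pan-endothelial scaling gave 15 towards cortex and 0 towards lung. The Wnt list as a whole did not pass (adjusted p = 0.13, and adjusted p = 0.799 with an estimated correlation).

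Tight junction genes were mostly not called, with 1 of 19 higher in cortex, 1 higher in lung and 17 not called, the same counts adjusted over the list alone. Cldn5, the main claudin of endothelium, lay at 12.64 ± 0.70 in cortex and 12.78 ± 0.13 in lung (adjusted p = 0.798). The adhesion protein Cxadr was 20.2-fold higher in cortex (adjusted p = 0.000189), and the cingulin relative Cgnl1 3.42-fold higher in lung (adjusted p = 0.0283). The call of Cgnl1 ended without any 1 of cortex 72 and 18 and lung 72, 22 and 19, at differences of -1.44 to -1.73 log2 units, and after pan-endothelial scaling, which gave 8 members higher in cortex and 0 in lung. Without cortex 19 the list had 2 members higher in lung, and without lung 72 it had 2 higher in cortex. The test of the list gave an adjusted p of 0.83, and adjusted p = 0.968 with an estimated correlation, with a median of -0.13, which became 1.10 after pan-endothelial scaling, and a mean of 0.09. Of 17 measured glycolytic genes, 4 rose in cortex and 2 in lung (5 and 2 adjusted over the list alone), and 11 were not called. The aldolase Aldoc was 30.0-fold higher in cortex and the lactate dehydrogenase subunit Ldhb 3.29-fold. Over the 4 cortex arrays, 0 of the 4 glycolytic genes higher in cortex rose with the pan-endothelial mean at a slope above 0.5, and neither did Cxadr. Among barrier transporters at least 2-fold higher in cortex, 9 of 11 did. The cells that these transcripts came from were not tested. The glycolysis list did not pass (adjusted p = 0.528, and adjusted p = 0.887 with an estimated correlation), with a median of -0.06 and a mean of 0.43, and pan-endothelial scaling gave 6 towards cortex and 0 towards lung with a median of 1.17. Its count towards lung fell to 0 without cortex 22, cortex 18 or lung 19 and to 1 without cortex 72, cortex 19, lung 72 or lung 18.

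Genes shared by endothelial cells of most vessels had lower means in cortex, most without a call, with a median of -1.13, which the pan-endothelial scaling by its construction brings near 0. Of the 26 members of the pan-endothelial list, 7 fell in cortex and 19 were not called (13 lower adjusted over the list alone), and 25 had a lower mean in cortex. The lectin Clec14a was 8.82-fold higher in lung (adjusted p = 0.000978), and the sialomucin Emcn 4.62-fold (adjusted p = 0.00829). Tek itself lay at 11.70 ± 0.84 in cortex and 12.93 ± 0.28 in lung (adjusted p = 0.0575), the adhesion molecule Pecam1 at 8.98 ± 1.06 and 10.46 ± 1.03 (adjusted p = 0.149) and the cadherin Cdh5 at 8.39 ± 1.09 and 9.65 ± 1.06 (adjusted p = 0.225). The list was shifted towards lung (adjusted p = 1.38e-05), and adjusted p = 0.651 with an estimated correlation. Its count of lower genes was 3 without cortex 72, 4 without lung 22 or lung 19 and 12 without cortex 19. With the sample number as a block it was 10, and Tek (limma adjusted p = 0.026) and Pecam1 (adjusted p = 0.0176) passed. Tek passed without cortex 22 (-1.48 log2 units) and without cortex 19 (-1.46 log2 units), and when arrays were centred on their medians (adjusted p = 0.044), and Pecam1 passed without lung 18 (-1.99 log2 units) and without both arrays numbered 18 (-1.54 log2 units, adjusted p = 0.0334).

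Components of caveolae and of vesicle transport differed in both directions. Their median of -0.85 turned to 0.38 after pan-endothelial scaling, against 1.14 over all genes. Of 18 measured members, 8 fell in cortex, 3 rose and 7 were not called (9 and 3 adjusted over the list alone). The caveolar coat protein Cavin2 was 27.4-fold higher in lung, at 12.66 ± 0.21 against 7.88 ± 1.30 in cortex (adjusted p = 0.000566), and Plvap, which forms the diaphragms of endothelial fenestrae and caveolae, 4.28-fold, at 12.56 ± 0.06 against 10.46 ± 0.92 (adjusted p = 0.00748). The reelin receptor Lrp8 was 8.35-fold higher in cortex. The list passed towards lung (adjusted p = 0.0346), but adjusted p = 0.654 with an estimated correlation, and it did not pass without cortex 72 (adjusted p = 0.0773), lung 72 (0.0814), lung 22 (0.0554) or lung 19 (0.071), or with the bioB covariate (0.0689). Without both arrays numbered 18 its count towards cortex was 1. Pan-endothelial scaling left 2 members higher in lung and gave 4 higher in cortex, and the call of Plvap ended (-0.87 log2 units). Of 14 genes for leukocyte adhesion, 5 were higher in lung, 1 higher in cortex and 8 not called (7 and 3 adjusted over the list alone). The hyaluronan receptor Cd44 was 13.3-fold higher in lung and the adhesion molecule Icam2 3.93-fold (adjusted p = 0.0219). Icam2 lost its call without cortex 72, lung 22 or lung 19, at -1.81 to -1.95 log2 units, and after pan-endothelial scaling (-0.74 log2 units), which left 1 member higher in lung, gave 4 higher in cortex and turned the median from -0.71 to 0.52. The count towards lung was 1 without cortex 72, lung 22 or lung 19, 2 without lung 72 and 3 without lung 18, and the count towards cortex was 2 without lung 72 or lung 19. The leukocyte adhesion list did not pass (adjusted p = 0.188, and adjusted p = 0.651 with an estimated correlation), but passed towards lung, relative to the other genes, after pan-endothelial scaling (0.0496).

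**Figure D2:**
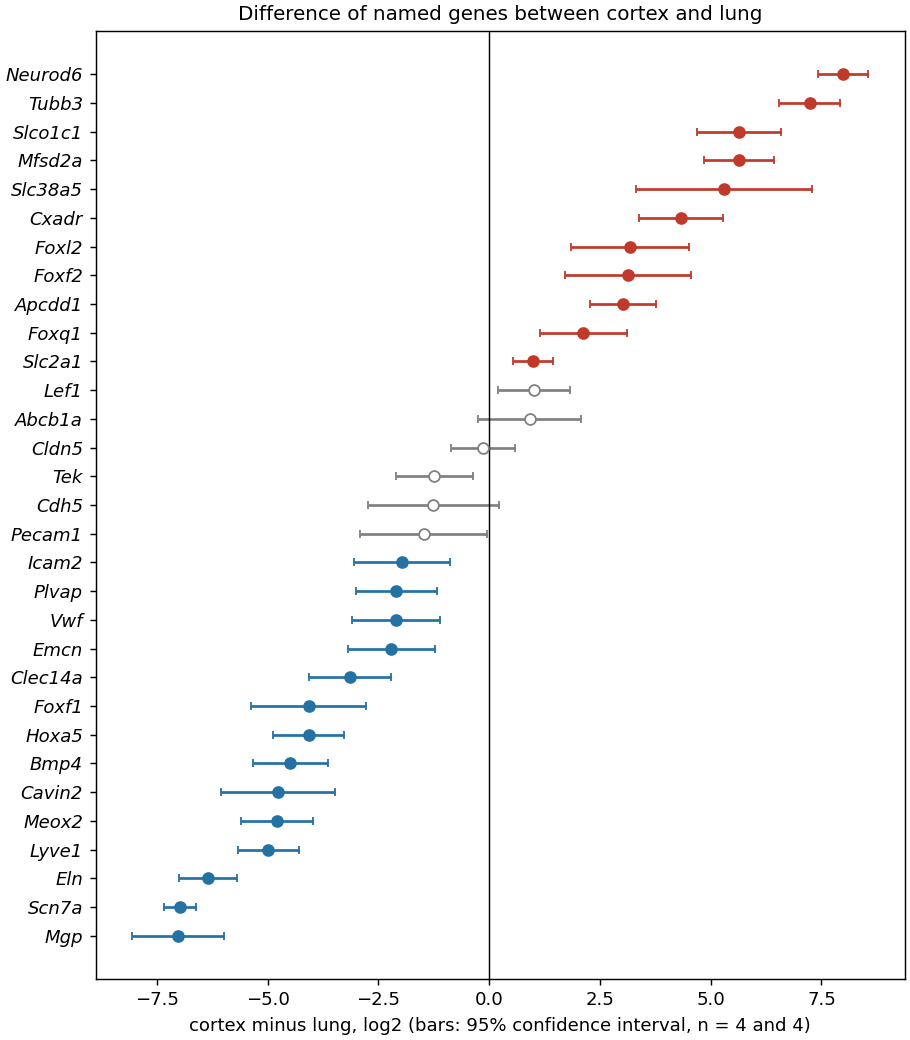
The horizontal axis gives the cortex minus lung difference on the log2 scale for 31 named genes, with bars for the 95% confidence interval over 4 arrays per tissue. Filled red and blue points are genes called higher in cortex and in lung, and open grey points did not pass. Mfsd2a, at 5.64, and Scn7a, at -6.98, lie far from 0, and the interval of Cldn5 includes 0.

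Genes known from lung vessels and from the lung field were higher in lung in part, and none of their 3 lists passed with an estimated correlation. Of 19 measured lung endothelial genes, 10 rose in lung, 3 rose in cortex and 6 were not called (12 and 3 adjusted over the list alone). Scn7a lay at 11.96 ± 0.14 in lung and 4.98 ± 0.23 in cortex (adjusted p = 1.74e-07), and Foxf1, a forkhead factor of lung mesenchyme and endothelium, at 10.69 ± 0.88 and 6.62 ± 1.01 (16.8-fold, adjusted p = 0.00151). The list passed towards lung (adjusted p = 0.000464, and adjusted p = 0.232 with an estimated correlation). Of 13 lung field transcription factors, 7 rose in lung and 6 were not called (9 adjusted over the list alone), with the homeobox factor Meox2 27.6-fold higher (adjusted p = 4.62e-05). That list passed with an adjusted p of 2.63e-05, and adjusted p = 0.486 with an estimated correlation. Of 33 Hox genes, 11 rose in lung and 22 were not called, with the same counts adjusted over the list alone. Hoxb5 was 34.9-fold higher and Hoxa5 16.9-fold, and the list passed (adjusted p = 1.72e-06, and adjusted p = 0.147 with an estimated correlation). Pan-endothelial scaling gave 4 lung endothelial genes, 4 lung field factors and 8 Hox genes higher in lung, against 3, 0 and 1 higher in cortex, with medians of -0.08, -0.27 and 0.68, so that the median of the Hox genes turned from -0.55. Of the 11 Hox genes left without dim probe sets, 7 were called. The mean of the fibroblast and mesenchyme list, another cell type that expresses many of these factors, was 8.51 ± 0.80 in the lung arrays and 6.48 ± 0.15 in the cortex arrays.

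Signalling genes of the TGF-beta and BMP pathways were mostly not called. Their median of -0.83 turned to 0.40 after pan-endothelial scaling, against 1.14 over all genes. Of 23 measured members, 7 were higher in lung, 1 higher in cortex and 15 not called (11 and 2 adjusted over the list alone). The ligands Bmp4 and Bmp6 were 22.5-fold (adjusted p = 7.93e-05) and 11.8-fold (adjusted p = 0.00181) higher in lung. The list passed (adjusted p = 0.00702, and adjusted p = 0.651 with an estimated correlation), and its 1 gene higher in cortex, Tgfbr1, named after its values were seen, lost its call without any 1 of cortex 72, 22, 19 and 18 and lung 72 and 22, leaving 0. Of 16 measured genes of the retinoid pathway, 4 were higher in lung, 2 higher in cortex and 10 not called (6 and 3 adjusted over the list alone). The retinoic acid-degrading enzyme Cyp26b1 was 17.3-fold higher in lung and the retinol carrier receptor Stra6 4.95-fold higher in cortex. The retinoid list did not pass (adjusted p = 0.13, and adjusted p = 0.651 with an estimated correlation). Its count towards lung was 2 without cortex 72 or lung 19, and its count towards cortex 1 without cortex 72, 19 or 18 or lung 22, 19 or 18. Immediate early and heat shock genes, which tissue dissociation can induce, were higher in lung for 5 of 22 members, and 17 were not called, with the same counts adjusted over the list alone. The cytokine signalling inhibitor Socs3 was 7.20-fold higher (adjusted p = 0.000253) and the heat shock gene Hspa1b 3.69-fold (adjusted p = 0.0401). Hspa1b lost its call without any 1 of cortex 72, 22, 19 and 18 and lung 72 and 22, at -1.80 to -2.06 log2 units, with the mean of its probe sets (-1.37) and after pan-endothelial scaling (-0.65). The dissociation list passed (adjusted p = 0.0346), but adjusted p = 0.651 with an estimated correlation, and it did not pass without cortex 72 (0.086), cortex 18 (0.0715), lung 72 (0.0591) or lung 19 (0.0892). Its count towards lung was 2 without cortex 72 or lung 72 and 3 without cortex 22, 19 or 18 or lung 22 or 19. Pan-endothelial scaling gave 3 TGF-beta and BMP genes, 1 retinoid gene and 1 dissociation gene higher in lung, against 4, 4 and 1 higher in cortex, and turned the medians of the retinoid list from -0.58 to 0.65 and of the dissociation list from -0.51 to 0.72.

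Markers of vessel types differed in part. After pan-endothelial scaling all lists had medians above 0 (arterial 0.67, venous 0.54, lymphatic 0.01) but below the 1.14 of all genes. Of 20 arterial genes, 5 rose in lung and 15 were not called (6 adjusted over the list alone), led by Mgp, at 12.06 ± 0.55 in lung and 5.04 ± 0.90 in cortex, and Fbln5, at 12.62 ± 0.62 and 6.50 ± 1.24. Both are also made by smooth muscle and fibroblasts. The arterial list passed (adjusted p = 0.0281, and adjusted p = 0.654 with an estimated correlation), but not without cortex 72 (0.0902), cortex 18 (0.102), lung 22 (0.0745) or lung 19 (0.071), and without cortex 19 it had 1 gene higher in cortex. Of 12 venous genes, 4 were higher in lung, 1 higher in cortex and 7 not called (6 and 3 adjusted over the list alone). Von Willebrand factor Vwf was 4.28-fold higher in lung (adjusted p = 0.0115), and the glutamine transporter Slc38a5, also in the transporter list, 39.4-fold higher in cortex (adjusted p = 0.00348). Vwf lost its call after pan-endothelial scaling (-0.87 log2 units). Without lung 72 or lung 19 the venous list had 2 genes higher in cortex. The venous list did not pass (adjusted p = 0.235, and adjusted p = 0.654 with an estimated correlation). Of 10 measured lymphatic endothelial genes, 5 were higher in lung, 1 higher in cortex and 4 not called (6 and 2 adjusted over the list alone). The hyaluronan receptor Lyve1 was 31.7-fold higher in lung (adjusted p = 1.8e-05) and the forkhead factor Foxc2 26.4-fold. The member higher in cortex was Pdpn, named after its values were seen, which neural progenitors also express. The lymphatic list passed (adjusted p = 0.0232, and adjusted p = 0.651 with an estimated correlation), but not without lung 19 (0.0613) or with the bioB covariate (0.0504). Its count towards lung was 3 without any 1 of cortex 72, 22 and 18 and lung 72, 22 and 19, and without lung 18 it had 2 genes higher in cortex. Pan-endothelial scaling gave 3 arterial, 0 venous and 2 lymphatic genes higher in lung, against 5, 3 and 2 higher in cortex.

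Genes of sprouting, basement membrane and proliferation were mostly not called. Of 15 tip cell genes, 1 rose in cortex, 2 in lung and 12 were not called, with the same counts adjusted over the list alone. The vasodilator peptide Adm was 4.80-fold higher in cortex (adjusted p = 0.00203), and the protocadherin Pcdh17 3.32-fold higher in lung (adjusted p = 0.00226), a call that ended after pan-endothelial scaling (-0.50 log2 units). The tip cell list gave an adjusted p of 0.663, and adjusted p = 0.964 with an estimated correlation, and the scaling gave 5 members towards cortex and 0 towards lung and turned its median from -0.39 to 0.85. Of 16 basement membrane genes, 4 were higher in lung, 1 higher in cortex and 11 not called (6 and 1 adjusted over the list alone). The collagen Col15a1 was 5.27-fold higher in lung (adjusted p = 0.014) and vitronectin, Vtn, 8.16-fold higher in cortex (adjusted p = 0.000496). Col15a1 lost its call after pan-endothelial scaling (-1.17 log2 units), which left 0 members higher in lung, gave 3 higher in cortex and turned the list's median from -0.52 to 0.71. The count towards lung was 1 without cortex 72 and 2 without any 1 lung array. This list did not pass (adjusted p = 0.147, and adjusted p = 0.84 with an estimated correlation), but passed without cortex 22 (0.0337) and without cortex 19 (0.013). Of 26 measured cell cycle genes, 3 were higher in lung and 23 not called, with the same counts adjusted over the list alone. After pan-endothelial scaling 8 were higher in cortex and 0 in lung, with the median moving from -0.05 to 1.18, near the 1.14 of all genes. The replication helicase subunits Mcm6 and Mcm3 were 1.58-fold (adjusted p = 0.0157) and 1.56-fold (adjusted p = 0.0233) higher in lung. Pan-endothelial scaling, which shifts every gene by the same amount, turned their differences to 0.57 and 0.59 log2 units without a call. Both values lay below the 1.14 of all genes. Mcm3 lost its call without cortex 72 (-0.63 log2 units) and without cortex 22 (-0.60 log2 units). The cell cycle list gave an adjusted p of 0.605, and adjusted p = 0.958 with an estimated correlation, and its count towards lung was 1 without cortex 22 and 0 without both arrays numbered 18.

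**Figure D3:**
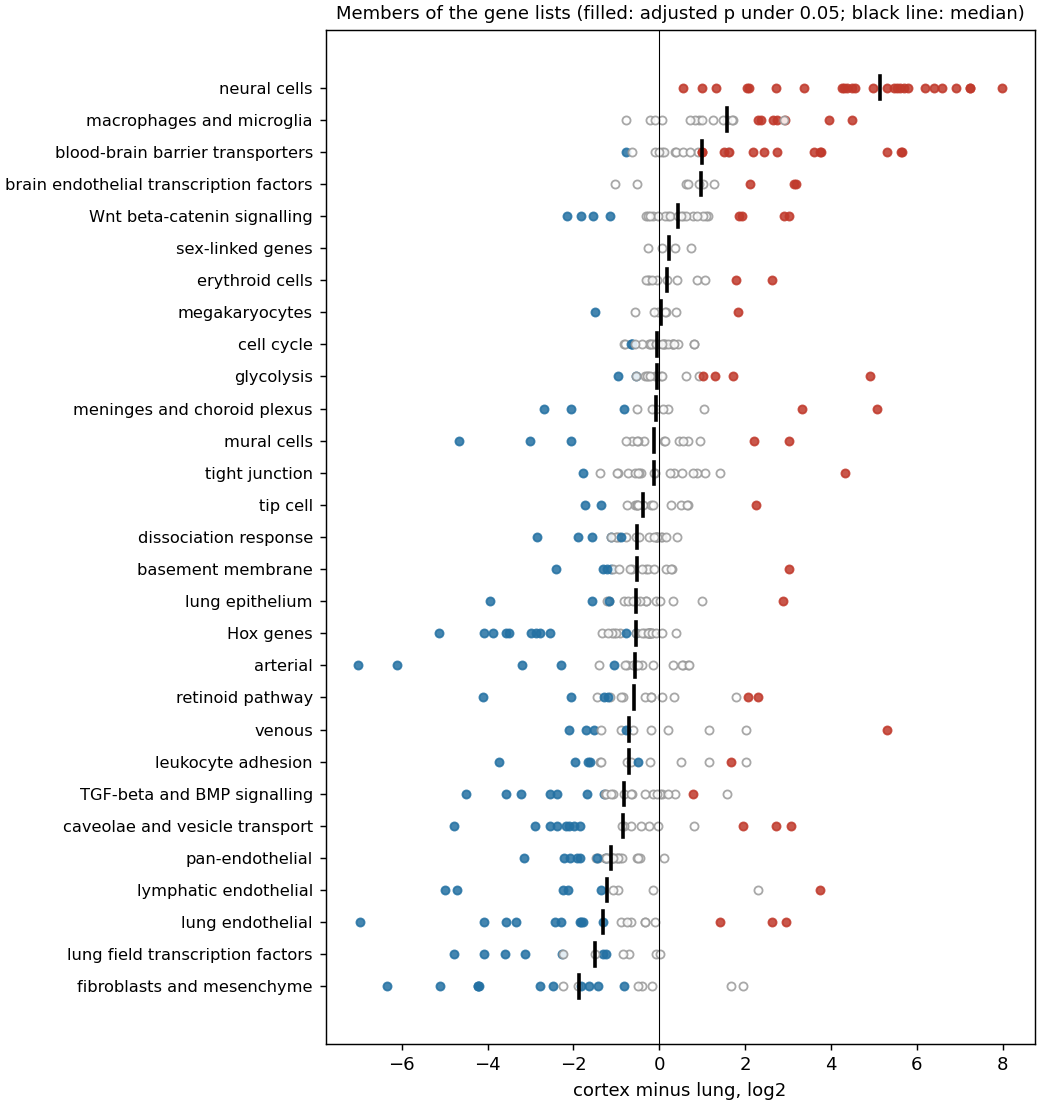
Each row is a gene list other than the solute carrier family, ordered by its median, and each point a member placed on the horizontal axis by its cortex minus lung difference on the log2 scale. Filled points passed an adjusted p under 0.05, red towards cortex and blue towards lung, and the black lines mark medians, from 5.14 for neural cells to -1.86 for fibroblasts and mesenchyme. After pan-endothelial scaling medians below 0 remain in the fibroblast, lung field and lung endothelial lists.

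Markers of other cell types were measured in both tissues. Of 21 genes of macrophages and microglia, 7 rose in cortex and 14 were not called (13 adjusted over the list alone). The complement gene C1qb was 22.4-fold higher, at 10.05 ± 1.99 against 5.57 ± 1.49 (adjusted p = 0.019), and the receptor Csf1r 15.5-fold, at 10.00 ± 2.10 against 6.05 ± 1.23 (adjusted p = 0.0293). The list passed towards cortex (adjusted p = 0.000131, and adjusted p = 0.651 with an estimated correlation). Its count depended on single arrays, with 14 genes called without cortex 18, 0 without cortex 72, 1 without cortex 22 or cortex 19, 2 without lung 22 or lung 19 and 3 without lung 18. With the sample number as a block it was 10. Pan-endothelial scaling gave 17 of 21 higher in cortex, with the median moving from 1.58 to 2.81. C1qb lost its call without cortex 72 (4.14 log2 units) and without lung 19 (4.44 log2 units), and Csf1r without any 1 of cortex 72, 22 and 19 and lung 22 and 18, at 3.46 to 3.77 log2 units. Of 11 measured erythroid genes, 2 rose in cortex and 9 were not called, with the same counts adjusted over the list alone. They were the embryonic globins Hba-x (6.17-fold, adjusted p = 0.017) and Hbb-y (3.43-fold, adjusted p = 0.00235), with Hbb-y at 13.05 ± 0.40 in cortex and 11.27 ± 0.43 in lung. Hba-x lost its call without both arrays numbered 18 (1.96 log2 units). The erythroid list did not pass (adjusted p = 0.291, and adjusted p = 0.654 with an estimated correlation), and the scaling gave 5 of its genes towards cortex. Of 8 measured megakaryocyte genes, 1 rose in cortex (Gp1bb, 3.56-fold), 1 in lung (Itgb3, 2.84-fold) and 6 were not called, with the same counts adjusted over the list alone. Itgb3 lost its call after pan-endothelial scaling (-0.27 log2 units) and without both arrays numbered 18 (-1.21 log2 units), and the list gave an adjusted p of 0.767, and adjusted p = 0.964 with an estimated correlation, with 2 genes towards cortex and 0 towards lung after the scaling.

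Fibroblast and mesenchyme genes were higher in lung for 11 of 18 measured members, and 7 were not called (14 higher in lung and 2 in cortex adjusted over the list alone). Eln lay at 13.25 ± 0.54 in lung and 6.91 ± 0.33 in cortex, and periostin, Postn, was 34.3-fold higher in lung (adjusted p = 0.00189). The list passed (adjusted p = 1.38e-05, and adjusted p = 0.528 with an estimated correlation). Its count towards lung was 7 without cortex 72, cortex 22 or lung 19, without lung 72 it had 2 members higher in cortex, and pan-endothelial scaling gave 6 higher in lung and 2 in cortex, with a median of -0.63. Of 16 mural cell genes, 3 were higher in lung, 2 higher in cortex and 11 not called (4 and 4 adjusted over the list alone), with smooth muscle actin Acta2 25.2-fold higher in lung and Vtn higher in cortex. The mural list gave an adjusted p of 0.99, and adjusted p = 0.995 with an estimated correlation, and its median of -0.12 and mean of -0.27 lay towards lung while its test statistic lay towards cortex. Pan-endothelial scaling gave 6 towards cortex and 2 towards lung, with a median of 1.11. The mural count towards cortex was 5 without lung 72 and 1 without any 1 of cortex 72 and 22 and lung 22, 19 and 18. Of 17 lung epithelial genes, 3 were higher in lung, 1 higher in cortex and 13 not called (4 and 1 adjusted over the list alone). The keratin Krt18 was 15.4-fold higher in lung, and Sox9, which neural progenitors also express, 7.38-fold higher in cortex. The epithelial list did not pass (adjusted p = 0.188, and adjusted p = 0.811 with an estimated correlation), passed without cortex 22 (0.0491) and with the bioB covariate (0.0364, with 7 genes higher in lung), and had 1 gene higher in lung without cortex 72, cortex 18 or lung 22. Pan-endothelial scaling gave 3 towards cortex and 1 towards lung and turned its median from -0.53 to 0.70. Of 11 genes of meninges and choroid plexus, tissues cleared from the cortex at dissection, 2 were higher in cortex, 3 higher in lung and 6 not called, with the same counts adjusted over the list alone. Transthyretin, Ttr, was 33.9-fold higher in cortex, at 11.02 ± 2.72 against 5.94 ± 0.74 (adjusted p = 0.0187), and the homeobox factor Otx2 9.96-fold (adjusted p = 0.00433). Ttr lost its call without cortex 72 (4.40 log2 units) and without lung 22 (4.95 log2 units), so that 1 gene remained higher in cortex there, and the count towards lung was 1 without any 1 of cortex 72, 22 and 18 and lung 19. That list gave an adjusted p of 0.96, and adjusted p = 0.98 with an estimated correlation, and its median of -0.07 and mean of 0.31 differed in sign. Pan-endothelial scaling gave 3 towards cortex and 1 towards lung, with a median of 1.16. None of the 4 measured sex-linked genes was called over all genes or over the list alone (limma, list p = 0.597, and adjusted p = 0.84 with an estimated correlation), and Xist lay at 12.44 ± 0.34 in cortex and 11.69 ± 0.59 in lung (adjusted p = 0.133), passing with the mean of all its probe sets (adjusted p = 0.0406) and after pan-endothelial scaling (1.98 log2 units), which called 2 of the 4.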

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

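Tests of the neural, pan-endothelial and macrophage patterns were chosen after the values were seen, and the counts over regrouped arrays before. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many called genes (3291, highest other 1). The same held for genes at least 2-fold apart (1 split, 2336, highest other 1) and for probe sets (1 split, 5475, highest other 0). Every other split put arrays of both tissues in each group, so the tissue difference widened the spread within groups and lowered the calls. With the groups of the description field, 42 genes had an unadjusted p under 0.05 (limma), where chance gives 909.65. The splits therefore decide nothing about chance.

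Neural transcripts reached 10.51 to 12.70 log2 units in cortex for such genes as Tbr1 and Tubb3. A candidate explanation is RNA of neural cells in the sorted cortex samples, although the sort on GFP should remove them. All 26 of 26 members were called, 0 of them in another list, but that count is the pattern itself and decides nothing between sources. Expression in the endothelial cells themselves would make these genes rise with the pan-endothelial mean over the 4 cortex arrays. They did not: the 90th percentile of their slopes was -0.036, against a median slope of 0.61 for the barrier transporters. This restates the order of array means seen before the test was chosen, over 4 arrays. The neural mean was 11.25 on cortex 72 and 18, where the pan-endothelial means were 9.64 and 9.30. It was lower on cortex 22 and 19, where the pan-endothelial means were 10.998 and 11.16. If the pan-endothelial mean follows the share of endothelial RNA, this argues against endothelial expression as the main source for these 26 genes. That condition was not tested. Neural RNA and transgene expression in neural cells stay open, and a smaller endothelial part is not excluded.

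The pan-endothelial genes lay lower in cortex for 25 of 26 members, which a lower share of endothelial RNA may explain, but that count is the pattern itself and decides nothing. Over the 4 cortex arrays the members moved together, with a median slope of 0.97 on the mean of the others. Such a share alone would lower all members by the same amount, if RMA compressed them evenly and no other sorted cells expressed them. Neither condition was tested. Of the members, 7 differed from the mean of the others at an adjusted p under 0.05 over the list (limma). Among them were Clec14a (-1.99 log2 units) and Flt1 (1.40 log2 units). Under those conditions this argues against a lower share as the whole cause. Both a lower share and a tissue difference in endothelial expression stay open for the shared part, since the design cannot separate them.

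Macrophage transcripts were higher on 3 of the 4 cortex arrays than on cortex 18. The list mean was 5.96 on cortex 18 and at least 8.03 on the others. Macrophages or microglia in the sorted cells are a candidate source. The sort on GFP should remove cells without the transgene's expression, but whether macrophages express it was not measured. That 19 of the 21 members, 0 of them in another list, were lowest on cortex 18 restates the low list mean and decides nothing. A lower signal on that array for all genes would be largely removed by the normalization by quantiles. The array median was 6.69 on cortex 18 and 6.67 to 6.72 on the other cortex arrays. The neural list lay 0.26 log2 units above the other 3 cortex arrays, so it did not share the fall. This cannot test a lower signal before normalization. Macrophages and other sources stay open.

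Single arrays far from the other 3 of their tissue were looked for in 202 groups of 4 (named genes and list means). Chance marks about 1 in 20 groups, 10.1 here, and 14 were found. On cortex 18, C1qb lay at 7.08 against at least 10.73 on the others, Csf1r at 6.89 against at least 10.63, and Socs3 at 6.78 against at least 7.91. On lung 18, Postn lay at 7.09, Pecam1 at 8.92 and Icam2 at 12.32, each the lowest, and Fendrr at 11.96, the highest. On lung 22, Lrp8 lay at 8.17, Apcdd1 at 9.10 and Abcb1a at 8.997, each the lowest. Pantr1 lay at 12.35 on cortex 19, the lowest, and at 5.48 on lung 72, the highest. Scn7a was lowest on cortex 72 (4.64), and Otx2 lowest on cortex 22 (8.17).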

How the results depend on the processing

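The pan-endothelial scaling, the omission of both arrays numbered 18 and the bioB covariate were chosen after the data were seen. The number of called genes ran from 2393 to 3081 when 1 array was left out, that of genes differing at least 2-fold from 1882 to 2437, that of probe sets from 3760 to 5001, and that of gene lists passing from 10 to 16. Other alternatives stayed within 1.5 times of the first 2 counts, at 3055 to 4437 and 2095 to 2570 for those planned, and at 2236 and 1879 without both arrays numbered 18 and 3959 and 2510 with the bioB covariate, with these exceptions. A threshold of 0.01 gave 1683 genes, and a test against a 2-fold difference 830, both by their stricter construction. Pan-endothelial scaling gave 5380 genes, all at least 2-fold apart (5380), with 97.4% towards cortex. limma gave every listed gene the same SE (0.587) there, so a call is a limit on the fold and the 2 counts are equal by construction. It removes a shift of -1.23 log2 units from every gene. With groups from the description field, limma called 0 genes, and 0 at least 2-fold, with 42 genes at an unadjusted p under 0.05. That grouping mixes 2 arrays of each tissue. An estimated correlation left 1 gene list.

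The numbers shared by cortex and lung samples were checked for pairing. Deviations from the tissue means correlated at 0.33 for number 72, -0.16 for 22, 0.01 for 19 and 0.31 for 18. Of 8 arrays, 4 correlated best with their own number. These values neither show nor exclude that the numbers pair the samples. The main fit, set beforehand without a block, was kept. With the sample number as a replicate block, 3143 genes were called, 2330 of them at least 2-fold apart, with 5147 probe sets and 14 gene lists, and Tek (adjusted p = 0.026) and Pecam1 (adjusted p = 0.0176) passed.

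Among the named genes, the differences of Mcm6 (0.57) and Mcm3 (0.59) changed sign under pan-endothelial scaling. Cldn5, not called in any of these, ran from -0.35 without cortex 22 to 0.17 without cortex 18, and turned to 0.22 without both arrays numbered 18 and to 1.10 under the scaling. The sign changes under the scaling follow from its removal of -1.23 log2 units from every gene. The scaled values of these genes lay below the 1.14 of all genes. The cause of the changes on leaving out arrays was not tested. For log2 arrays, signal near the lower end limits what can be seen. The bioB controls do not measure that end, since they lay above the array medians of 6.59 to 6.72. They ranged from 7.67 to 9.29 after normalization, highest on lung 18.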

Other observations

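The 10 gene families were chosen after the other results were seen, so their counts are descriptions and no test of a family is given. Pan-endothelial scaling called 5242 of all 18193 genes towards cortex and 138 towards lung, and the scaled counts of families carry this shift. The test of slopes in the last paragraph was written before its result was seen.

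Genes of elastic fibres were higher in lung for 11 of 17 measured members and 6 were not called. Besides Eln, Fbln5 and Lox these included the microfibril genes Mfap5 (18.5-fold) and Fbn2 (10.5-fold, at 12.32 ± 0.14 against 8.93 ± 0.25, n = 4 each). After pan-endothelial scaling 6 members were called towards lung and 3 towards cortex. Collagens were higher in lung for 17 of 42 members, led by Col3a1 and Col1a2 (18.6-fold each), and higher in cortex for 4, among them Col22a1 (12.7-fold), and scaling gave 6 towards lung and 4 towards cortex. Eln, Mfap5, Col1a2 and Col3a1 are also in the fibroblast and mesenchyme list, whose mean was 8.51 ± 0.80 in lung and 6.48 ± 0.15 in cortex. Interferon-inducible and MHC class I genes were higher in lung for 4 of 22, Irf1 (6.86-fold), Ifitm3 (5.58-fold), Ifitm2 (4.52-fold) and Bst2 (3.94-fold), and scaling gave 1 each way. Vasoactive peptide genes and their receptors were higher in lung for 5 of 18, among them endothelin Edn1 (5.61-fold) and the receptor Calcrl (5.43-fold), while Adm was higher in cortex, and scaling gave 0 towards lung and 2 towards cortex.

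Semaphorins and plexins, guidance genes of axons and vessels, were higher in cortex for 12 of 30 members, led by Sema5b (18.8-fold) and Sema5a (10.6-fold), and higher in lung for 3, and scaling gave 16 and 0. Notch pathway genes were higher in cortex for 5 of 22, led by Hes5 (4.28-fold), which is also a neural progenitor gene, and scaling gave 12 towards cortex and 0 towards lung. The mean of the neural list was 11.05 ± 0.26 in cortex and 6.36 ± 0.15 in lung. Potassium channels gave 18 of 84 towards cortex and 6 towards lung, and 37 and 1 after scaling. Serpins gave 1 of 40 towards cortex and 4 towards lung, and 2 and 1 after scaling. Cholesterol synthesis genes gave 2 of 18 towards cortex and 1 towards lung, and 11 and 0 after scaling. Of 43 ribosomal protein genes, 1 was called, Rps4l, higher in lung (2.36-fold, limma adjusted p = 0.00811), and 0 after scaling.

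The second principal component, 17.5% of the variance, ran from -61.4 on lung 72 and -33.5 on lung 19 to 29.9 on lung 22 and 57.0 on lung 18. The bioB hybridization controls lay at 7.67, 8.18, 9.08 and 9.29 on these arrays, and the 3' minus 5' difference of beta-actin was 0.99 on lung 18 and 0.36 to 0.55 on the other 7 arrays. With the bioB level as a covariate, 3959 genes were called.

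A hypothesis was that genes higher in cortex that follow the pan-endothelial mean over the 4 cortex arrays may be picked out as endothelial. Of the 1435 genes at least 2-fold higher in cortex, 65 had a slope above 0.5, and 1251 had a slope below 0. The 4 orders that exchanged both arrays of high mean for those of low mean gave 295 to 336, but these orders turn most slopes around. The 16 mixed orders gave a median of 31 and at most 110. The comparison of orders decides nothing. The macrophage list had the same median slope as the pan-endothelial list, 0.97, with a wider spread (10th to 90th percentile 0.32 to 1.45 against 0.78 to 1.22), and 7 of its 7 genes called at least 2-fold higher in cortex had slopes above 0.5, so a slope above 0.5 did not set endothelial genes apart. Among the 65, outside the lists, the largest differences were those of Apod (69.7-fold), Spock2 (49.8-fold), Foxl2os (35.1-fold), Far2 (26.5-fold) and Htra3 (24.2-fold), and Mpeg1 and Ccl3, genes known from macrophages, were also among them.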
